A study of Mus musculus with 19 samples.

How the data were processed

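Liver total RNA of mice, in 19 libraries of 4 groups (control or PLIN5 ASO, fasted or re-fed) was sequenced; per the labels it was extracted with the RNeasy kit and made into libraries by standard Illumina protocols. The submitters' processing notes name FastQC, HISAT2 2.0.2, Cuffdiff 2.2.1, edgeR and Subread, the last and edgeR without versions, and the genome builds mm10 and GRCm38, with no role or order for any. The annotation used, the strand setting and the treatment of reads that match several genes are not given in the sources used here. The authors deposited a table of read counts per gene symbol, whose values are whole numbers, and a table of FPKM (fragments per kilobase, scaled to 1e6 mapped fragments) per gene symbol; any further scaling of the deposited FPKM is not given. There were 24421 gene symbols with counts and 24347 with FPKM. Of the former 27 had the form of dates and could not be matched to a gene, and 2 of them occurred more than once.

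Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM normalization, the filterByExpr filter by group (default minimum count of 10), 1 fit of all 19 libraries with a mean per group, and the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the 13293 genes tested and a threshold of 0.05. Tested genes held at least 99.96% of each library's counts. Total counts per library were 24.9 to 66.9 in units of 1e6. Levels are CPM on TMM-scaled libraries, with the SD between libraries. The 5 comparisons were PLIN5 ASO against control ASO in fasted and in re-fed liver, re-fed against fasted under each ASO, and the interaction. The same fit was tested on simulated data, with 200 changed genes at known folds: 50.6%, 76.4% and 92.6% of the genes set at 1.5, 2 and 3-fold were found in the fasted ASO comparison, 61.5%, 81.8% and 92.5% in the re-fed one, 44.1%, 78.8% and 89.3% for re-feeding under control ASO, 54.3%, 77.8% and 94.0% under PLIN5 ASO and 17.4%, 60.3% and 76.2% for the interaction. Between 3.1% and 7.7% of the genes called there were unchanged ones, a raised list was found, and 0 of 20 unchanged lists were called. Genes were simulated independently of each other and with no library set apart from its group. The list result therefore does not show how often lists are called wrongly where genes are correlated.

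Gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and adjusted over the 29 lists within a comparison, and again with the correlation estimated from the data and with fry, which tests whether a list's genes move one way without comparing them with other genes. The 29 lists, of 642 genes, of which 640 were in the count table, were autophagy core, lysosome, fatty acid oxidation and ketogenesis, fatty acid synthesis, cholesterol synthesis, gluconeogenesis and fasting response, amino acid catabolism and urea cycle, lipid droplet proteins and lipases, inflammatory signalling, acute phase, interferon response, unfolded protein and integrated stress response, oxidative phosphorylation, sirtuins and mitochondrial biogenesis regulators, bile acid synthesis and transport, xenobiotic metabolism, NRF2 antioxidant response, p53 targets, circadian clock, ribosome biogenesis, cell cycle and immediate early genes. To these come 7 marker lists: Kupffer cell and macrophage, neutrophil and monocyte, lymphocyte, liver endothelial, stellate and fibroblast, cholangiocyte, and pancreas, fat and blood markers. Itgam is in both the macrophage and the neutrophil markers, Me1, Foxo1 and Ppargc1a are each in a pair of the other lists, and Plin5 is in no list.

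The groups, comparisons, tests, lists, alternative settings and the rule for named genes were set before the data were examined. The rule took, per comparison, the 8 largest rises and 8 largest falls among genes called with a mean of at least 2 CPM in 1 of the groups compared (5 and 5 for re-feeding under PLIN5 ASO and the interaction), leaving out names of the form Gm and digits or ending in Rik. It also took up to 4 members of each list with the smallest unadjusted p, and in any comparison Plin5, Plin2, Sirt1, Ppargc1a, Ulk1, Becn1, Atg7, Map1lc3b, Sqstm1, Tfeb, Lamp1, Tnf, Il6, Il1b, Ccl2 and Nfkb1. Positions and transcript lengths are from the GENCODE annotation of mouse genome build GRCm38, matched by symbol; lengths were known for 96.2% of the genes tested.

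The alternatives set beforehand were RLE size factors; no filter on low counts or a stricter one (1 CPM in 4 libraries); DESeq2 1.42.0; a fit of only the groups compared; the replicate number as a factor; leaving out each library in turn; and limma on log2 of the deposited FPKM plus 1 or 0.1, with a mean FPKM of at least 0.5 or no filter. Chosen after seeing the data were: fasted control ASO 3 and 4 as 1 sample; leaving out the 4 clock-shifted libraries; the clock score as a covariate; and offsets that take out each library's trend with transcript length in 25 bins. Where more than 100 other splits of the libraries into groups were possible, 100 were drawn with a fixed seed. No library was left out of the main results, and FPKM served for alternatives only.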

Results

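Liver RNA was sequenced from 19 mouse libraries. The mice were on a purified diet and had received 2 injections a week for 3 weeks of an antisense oligonucleotide (ASO, a short synthetic nucleic acid that lowers the RNA it pairs with). The ASO was directed at Plin5, which encodes the lipid droplet coat protein perilipin 5, or was a control. Livers were taken after an overnight fast or after a fast and 4 h of re-feeding. The groups held 4 libraries for fasted control ASO (numbered 1, 3, 4 and 5 in the labels), 5 for fasted PLIN5 ASO, 5 for re-fed control ASO and 5 for re-fed PLIN5 ASO. The labels do not say whether replicates are separate animals. The series design speaks of mice, and each library was treated as 1 mouse. Total counts per library, in units of 1e6, were 28.2 to 33.9 in fasted control ASO, 28.7 to 31.8 in fasted PLIN5 ASO, 25.8 to 30.8 in re-fed control ASO and 24.9 to 66.9 in re-fed PLIN5 ASO, where library 5 held 66.9. After the filter on low counts 13293 genes were tested, with a biological coefficient of variation of 19.3%. Clock genes, looked at after the values were seen, set 4 libraries apart. Arntl, which encodes a core activator of the circadian clock, stood at 14.6 and 15 CPM (counts scaled to 1e6 per library) in fasted PLIN5 ASO 3 and 5. It stood at 23.8 and 45.0 CPM in re-fed control ASO 3 and 5, against 0.566 to 4.87 CPM in the other 15 libraries. Dbp, a clock output gene, stood at 4.80, 18.9, 11.5 and 1.82 CPM in these 4 libraries, called clock-shifted from here on, and at 36.3 to 160 CPM in the others. Fasted control ASO 3 and 4 lay closer together than any other of the 36 pairs of libraries within a group, with a chi-square per degree of freedom of 3.27 against 19.5 for the next pair. The labels do not settle whether these are 2 mice, so n = 4 in fasted control ASO holds only if they are.

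Plin5 RNA was lower in every PLIN5 ASO library than in every control ASO library of the same feeding state. The gene lies on chromosome 17 at 56111601 to 56117596 on the minus strand of GRCm38, with 9 exons in its longest annotated form. In fasted liver it stood at 9.13 CPM ± 3.44 (SD, n = 5) with PLIN5 ASO and 36.9 CPM ± 1.52 (SD, n = 4) with control ASO, a log2 fold change of -2.01 (SE 0.28, 95% confidence interval -2.60 to -1.43, adjusted p = 0.00257 in edgeR's quasi-likelihood test). Single fasted libraries held 7.69, 6.15, 12.6, 6.14 and 13.1 CPM with PLIN5 ASO, against 35.1, 36.3, 38.5 and 37.8 CPM with control ASO. In re-fed liver Plin5 stood at 7.74 CPM ± 3.20 (SD, n = 5) against 37.5 CPM ± 10.8 (SD, n = 5), a log2 fold change of -2.28 (SE 0.27, 95% confidence interval -2.86 to -1.71, adjusted p = 0.00119). Single re-fed libraries held 9.98, 11.8, 3.91, 5.54 and 7.51 CPM with PLIN5 ASO, against 27.3, 51.8, 45.4, 28.3 and 34.8 CPM with control ASO. The fall did not differ detectably between the feeding states (difference -0.27 on the log2 scale, SE 0.39, adjusted p = 0.763). Re-feeding itself left Plin5 at a log2 fold change of 0.02 with control ASO (SE 0.27, adjusted p = 0.968) and -0.24 with PLIN5 ASO (SE 0.27, adjusted p = 0.634).

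**Figure D1:**
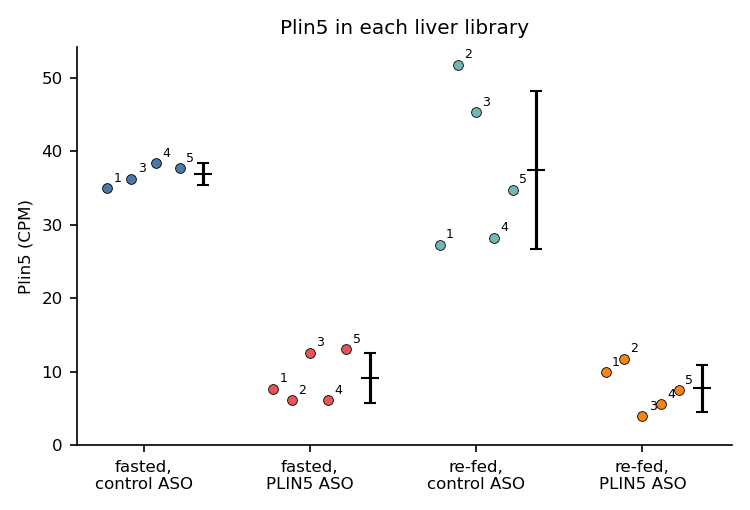
Plin5 in CPM (vertical axis) in each library of the 4 groups; points are libraries with their number, and bars give the group mean ± SD (n = 4, 5, 5 and 5). PLIN5 ASO libraries lie between 3.91 and 13.1 CPM and control ASO libraries between 27.3 and 51.8 CPM.

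Fasted liver with PLIN5 ASO against fasted liver with control ASO asks what PLIN5 ASO changes in the state that the series title names. The labels name no second oligonucleotide against Plin5. In this and the re-fed ASO comparison, effects of lower Plin5 therefore cannot be told apart from other effects of the oligonucleotide. The largest rises were in acute phase genes, which liver secretes or expresses in inflammation. Saa2 rose from 34.0 CPM ± 18.9 (SD, n = 4) to 1857 CPM ± 1868 (SD, n = 5), a log2 fold change of 5.77 (SE 1.19, adjusted p = 0.0258). Saa1 rose by 4.80 (SE 1.11, adjusted p = 0.0373) and Lcn2, the gene of the iron-carrier binding protein lipocalin 2, by 5.02 (SE 0.83, adjusted p = 0.00707). The rise was uneven between mice: Saa1 held 4170, 4860 and 2174 CPM in PLIN5 ASO 1, 3 and 5. It held 40.6 and 121 CPM in PLIN5 ASO 2 and 4, and 46.5 to 152 CPM in the 4 controls. Lcn2 was above every control in 5 of 5 libraries, at 332, 10.1, 540, 25.5 and 222 CPM against 6.12 to 8.25 CPM. Apcs (1.87, SE 0.37, adjusted p = 0.0235), Fgl1 (1.86, SE 0.38, adjusted p = 0.0248) and the metallothionein gene Mt2 (2.90, SE 0.61, adjusted p = 0.0258) rose as well. Asns, the asparagine synthetase gene, rose by 2.91 (SE 0.66, adjusted p = 0.0345), and Wfdc17 rose from 4.41 CPM ± 0.222 (SD, n = 4) to 12.8 CPM ± 1.74 (SD, n = 5; log2 fold change 1.54, adjusted p = 0.001). Beside Plin5, the largest falls were in Ncam2 (-2.19, SE 0.32, adjusted p = 0.00294), Hamp2 (-2.18, SE 0.49, adjusted p = 0.0344) and Btbd19 (-1.72, SE 0.29). Smaller falls were those of Gsta2 (-1.42, SE 0.34), Plk2 (-1.38, SE 0.18, adjusted p = 0.001) and Dusp6, which encodes an ERK phosphatase (-1.20, SE 0.22). Saa1 (chromosome 7, 46740497 to 46742980, minus strand) and Saa2 (46751790 to 46754313, plus strand) are close paralogs, as are Mt1 and Mt2. How reads matching several genes were counted is not given in the sources used here. In all, 156 of 13293 genes changed (80 rose, 76 fell; 36 and 19 of them at least 2-fold).

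Single libraries weigh on the fasted gene calls. Of the 8 largest rises and 8 largest falls, Lcn2, Wfdc17, Ncam2, Plin5, Btbd19 and Plk2 passed in every run that left out 1 library. Calls were lost for 8, 8, 9 and 10 of the 16 without fasted control ASO 1, 3, 4 and 5, and for 4, 8, 2 and 6 without PLIN5 ASO 1, 3, 4 and 5. The highest adjusted p so reached was 0.123 for Saa1 (0.000154 to 0.235 over all its alternatives), 0.077 for Saa2 (2.21e-06 to 0.171), 0.133 for Asns (0.00117 to 0.133), 0.0887 for Mt2 (0.00102 to 0.0887) and 0.144 for Gsta2 (0.00444 to 0.149). The number of genes changed was 46, 40, 30 and 24 without fasted control ASO 1, 3, 4 and 5, and 64, 102 and 43 without PLIN5 ASO 3, 4 and 5. With control ASO 3 and 4 taken as 1 sample 36 genes passed, 8 of the 16 among them; without the clock-shifted libraries 115 passed, 12 of the 16 among them. Of all 28 genes called that the rule takes in this comparison, list members such as Cyp1a2, Col1a2 and C1qb included, 7 passed in every run that left out 1 library, 9 with control ASO 3 and 4 as 1 sample and 14 without the clock-shifted libraries.

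Of 29 gene lists, 6 moved up and 6 down in fasted PLIN5 ASO liver under a preset correlation, and none passed with an estimated correlation (camera). In the acute phase list 9 of 25 genes rose (16 rose and 2 fell, adjusted over the list alone; median log2 fold change 0.81), with Serpina3n at 0.74 (SE 0.15, adjusted p = 0.0241) beside Lcn2, Apcs and Saa2. The list moved up (adjusted p = 3.65e-13, and adjusted p = 0.154 with an estimated correlation). Among stellate cell and fibroblast markers 3 of 14 rose (6 adjusted over the list alone): the collagen genes Col1a2 (1.06, SE 0.22) and Col3a1 (1.15, SE 0.26) and the matrix gene Lum (1.10, SE 0.24). That list moved up as well (adjusted p = 1.12e-07, and adjusted p = 0.154 with an estimated correlation). Among Kupffer cell and macrophage markers the complement genes C1qb (1.03, SE 0.24) and C1qa (0.89, SE 0.21) rose, 2 of 16 (6 adjusted over the list alone). The list moved up (adjusted p = 9.5e-07, and adjusted p = 0.526 with an estimated correlation). Its library scores were highest in the clock-shifted PLIN5 ASO 3 and 5 (1.14 and 0.74), against -0.35 to -0.01 in the other 3 of the group. Stellate cell (0.70 and 0.65), neutrophil and monocyte (1.02 and 0.73) and lymphocyte markers (0.94 and 0.45) were highest in the same 2 libraries, with stellate scores of -0.15, -0.21 and 0.44 in PLIN5 ASO 1, 2 and 4. Without the clock-shifted libraries the list's adjusted p was 0.275 (6.45e-10 to 0.526 over all alternatives). Liver endothelial markers moved the other way, with 0 of 16 called by edgeR (1 fell adjusted over the list alone; median -0.33; adjusted p = 0.00121, and adjusted p = 0.578 with an estimated correlation).

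**Figure D2:**
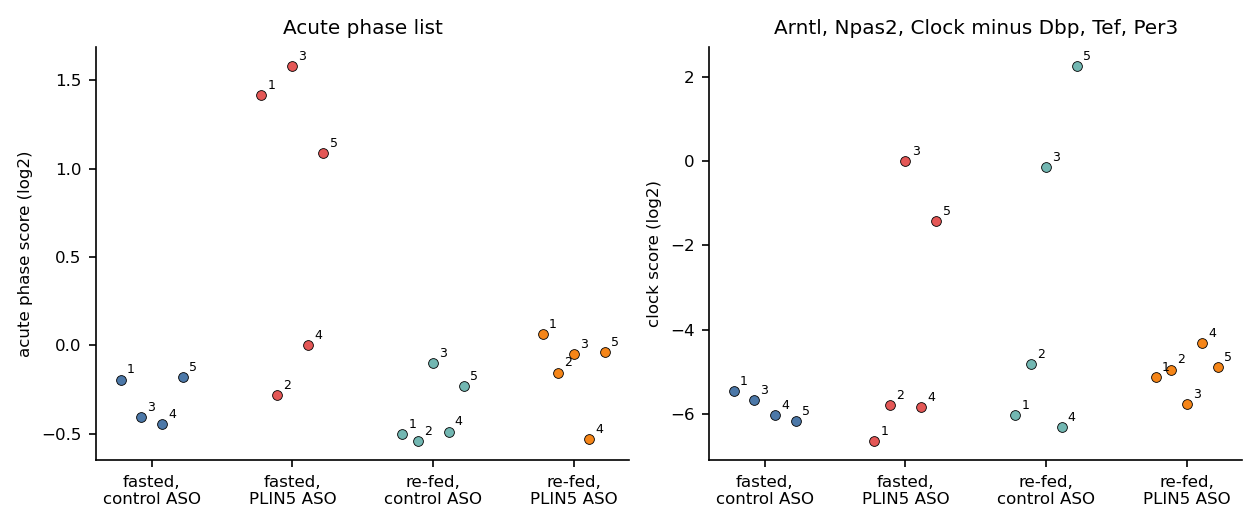
Left, mean log2 deviation of the acute phase list in each library; right, clock score (mean log2 CPM of Arntl, Npas2 and Clock minus that of Dbp, Tef and Per3) in each library, by group with the library number. The acute phase score lies at 1.42, 1.58 and 1.09 in fasted PLIN5 ASO 1, 3 and 5, and the clock score at -1.43 to 2.26 in the 4 clock-shifted libraries and at -6.65 to -4.31 in the other 15.

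Among metabolic lists in fasted liver, xenobiotic metabolism fell in 2 of 20 genes, both cytochrome P450 genes: Cyp1a2 (-0.78, SE 0.12, adjusted p = 0.00294) and Cyp2c50 (-0.59, SE 0.13, adjusted p = 0.0314). With 1 rise and 6 falls adjusted over the list alone, the list moved down (adjusted p = 0.000884, and adjusted p = 0.569 with an estimated correlation). Oxidative phosphorylation moved down with 0 of 27 genes called (median -0.13; adjusted p = 2.02e-05, and adjusted p = 0.578 with an estimated correlation). Cholesterol synthesis moved up with 0 of 25 (5 rose adjusted over the list alone; adjusted p = 0.000884, and adjusted p = 0.578 with an estimated correlation). The p53 target list moved down with Plk2 and Btg2 (-0.94, SE 0.21) of 18 genes (adjusted p = 0.0031, and adjusted p = 0.154 with an estimated correlation). The NRF2 antioxidant list moved down with Nfe2l2 itself (-0.42, SE 0.09) of 15 (adjusted p = 0.00643, and adjusted p = 0.154 with an estimated correlation). Immediate early genes moved down (0 of 15, 2 adjusted over the list alone; adjusted p = 0.00643, and adjusted p = 0.522 with an estimated correlation). The interferon response moved up (0 of 31, 3 adjusted over the list alone; adjusted p = 0.00222, and adjusted p = 0.578 with an estimated correlation). Gluconeogenesis and the fasting response did so too (0 of 16; adjusted p = 0.0155, and adjusted p = 0.487 with an estimated correlation). Otc, of the urea cycle, rose by 0.34 (SE 0.07) and Vcam1, an adhesion molecule gene, by 1.19 (SE 0.27), within lists that did not pass. Those 17 were fatty acid synthesis (adjusted p = 0.0682), neutrophil and monocyte markers (0.0682), lipid droplet proteins and lipases (0.138), circadian clock (0.34), lymphocyte markers (0.34), amino acid catabolism and urea cycle (0.34), sirtuins and mitochondrial biogenesis regulators (0.475) and fatty acid oxidation and ketogenesis (0.526). They were also unfolded protein and integrated stress response (0.59), autophagy core (0.704), bile acid synthesis and transport (0.744), lysosome (0.746), inflammatory signalling (0.817), ribosome biogenesis (0.888), cell cycle (0.956), pancreas, fat and blood markers (0.971) and cholangiocyte markers (0.971). Median, mean and test differed in sign for the circadian clock (-0.08, 0.02, down), pancreas, fat and blood markers (0.01, 0.40, down) and cholangiocyte markers (0.17, -0.06, up). The interferon call was lost without control ASO 5 (adjusted p = 0.182; 7.4e-06 to 0.578 over all alternatives). The gluconeogenesis call was lost without control ASO 1 (0.096), control ASO 5 (0.0558) and PLIN5 ASO 2 (0.0862; 0.00285 to 0.487 over all). Without the clock-shifted libraries the adjusted p was 0.119 for oxidative phosphorylation (3.43e-07 to 0.578 over all) and 0.201 for xenobiotic metabolism (1.99e-06 to 0.569 over all).

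In re-fed liver, PLIN5 ASO against control ASO gave 183 changed genes (108 rose, 75 fell; 4 and 19 at least 2-fold). A fit of only the 2 groups compared gave 4 genes and DESeq2 588. The metallothionein genes rose most: Mt2 (chromosome 8, 94172664 to 94173568, plus strand) from 1.47 CPM ± 0.537 (SD, n = 5) to 18.1 CPM ± 18.1 (SD, n = 5), a log2 fold change of 3.62 (SE 0.64, adjusted p = 0.0126). Mt1 rose by 2.82 (SE 0.54, adjusted p = 0.0169), and each was above every control in 4 of 5 libraries. The other large rises were LOC100504703 (1.14, SE 0.24), Armcx4 (0.95, SE 0.22), Nlrp12 (0.92, SE 0.20), AI413582 (0.86, SE 0.21), Npm3 (0.80, SE 0.15) and Fbxo36 (0.75, SE 0.16), with adjusted p of 0.0166 to 0.049. The largest falls were in the immediate early genes Fos (-3.43, SE 0.83, adjusted p = 0.0442), Egr1 (-2.55, SE 0.60, adjusted p = 0.0412) and Nr4a1 (-2.34, SE 0.53, adjusted p = 0.0348). Fos held 3.34 CPM ± 1.22 (SD, n = 5) against 35.4 CPM ± 56.9 (SD, n = 5). Re-fed control ASO 5 alone held 136 CPM of Fos and 109 CPM of Egr1. Slc13a2, a citrate carrier gene (-2.28, SE 0.46, adjusted p = 0.0211), Ncam2 (-2.14, SE 0.30, adjusted p = 0.00278), Rnf125 (-1.54, SE 0.35, adjusted p = 0.0364) and Tspyl4 (-1.46, SE 0.28, adjusted p = 0.0166) fell as well, beside Plin5. Of these 16 genes, Mt2, Mt1, Npm3, Plin5 and Ncam2 passed in every run that left out 1 library. Calls were lost for 8, 1, 4, 1 and 10 of the 16 without re-fed control ASO 1 to 5, and for 7, 11, 7, 4 and 4 without PLIN5 ASO 1 to 5. The adjusted p so reached was up to 0.191 for Fos (0.00233 to 0.247 over all its alternatives) and 0.143 for Egr1 (0.00339 to 0.199). The number of genes changed was 63, 333 and 62 without re-fed control ASO 1, 4 and 5, 65 and 45 without PLIN5 ASO 1 and 2, and 45 without the clock-shifted libraries, where 3 of the 16 passed. Of all 20 genes called that the rule takes here, 7 passed in every run that left out 1 library and 6 without the clock-shifted libraries.

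Transcript length moved with the ASO in re-fed liver. Genes called higher had a median transcript length of 936 nt and genes called lower one of 4648 nt, and across all genes with a known length the log2 fold change fell with length (Spearman's rho -0.332 across 12783 genes, which are not independent replicates). Genes under 1000 nt had a median log2 fold change of 0.17 and genes over 5000 nt one of -0.14. Long minus short transcripts averaged 0.20 (log2) in the 5 re-fed control libraries and -0.12 in the 5 re-fed PLIN5 ASO libraries (exact permutation p = 0.00794, two-sided, 252 splits), 1 of 4 pairs of groups so tested. In fasted liver, with rho 0.02, the groups averaged -0.05 and -0.04 (exact permutation p = 0.762). With the length trend of each library taken out, an alternative chosen after the values were seen, 39 genes passed in re-fed liver. Of the 16 genes above, 9 were among them.

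**Figure D3:**
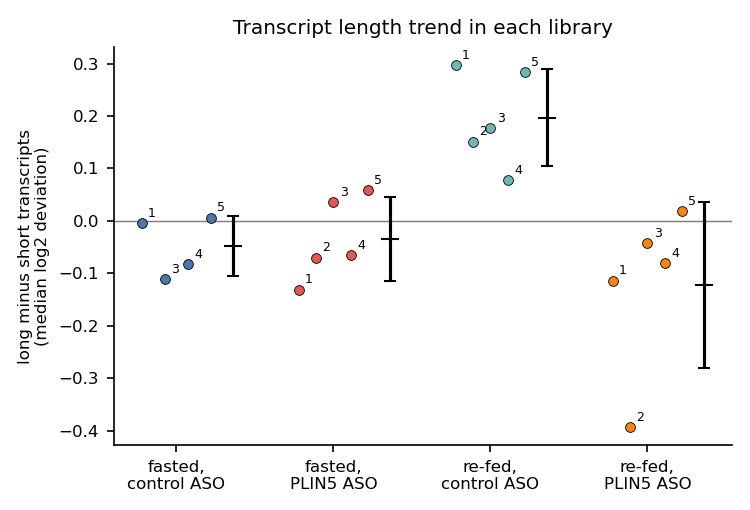
Median log2 deviation of transcripts over 5000 nt minus that of transcripts under 1000 nt in each library (points, with library number), by group, with mean ± SD (bars; n = 4, 5, 5 and 5). Re-fed control ASO libraries lie at 0.08 to 0.30 and re-fed PLIN5 ASO libraries at -0.39 to 0.02.

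Of the 29 lists, 5 moved up and 6 down in re-fed PLIN5 ASO liver, none of them with an estimated correlation. Liver endothelial markers moved down with 1 of 16 genes, Kdr, a VEGF receptor gene (-1.06, SE 0.24, adjusted p = 0.0348; 6 fell adjusted over the list alone; list adjusted p = 4.64e-05, and adjusted p = 0.663 with an estimated correlation). Fatty acid synthesis (0 of 22, 3 fell adjusted over the list alone; median -0.37; adjusted p = 0.000197) and cholesterol synthesis (0 of 25, 4 fell adjusted over the list alone; median -0.35; adjusted p = 0.000183) moved down, each with an adjusted p = 0.663 with an estimated correlation. Immediate early genes moved down with Fos, Egr1 and Nr4a1 of 15 (6 adjusted over the list alone; adjusted p = 0.00229, and adjusted p = 0.663 with an estimated correlation). The unfolded protein and integrated stress response (0 of 26; adjusted p = 0.0135) and the cell cycle (0 of 21; adjusted p = 0.036) moved down too, with adjusted p of 0.677 and 0.663 with an estimated correlation. Up moved the interferon response (0 of 31; adjusted p = 0.00205), lipid droplet proteins and lipases (0 of 20; 0.0228), fatty acid oxidation and ketogenesis (0 of 31; 0.0228), oxidative phosphorylation (0 of 27; 0.027) and ribosome biogenesis (0 of 27; 0.0493). With an estimated correlation their adjusted p was 0.677 to 0.742, and 0 genes were called adjusted over each of these lists alone. Abcc2, a canalicular export pump gene, fell (-0.42, SE 0.09, adjusted p = 0.024) and Otc rose (0.40, SE 0.07, adjusted p = 0.0126) in lists that did not pass. Those 18 lists had adjusted p of 0.0511 (p53 targets, where Plk2 fell, and lysosome) to 0.942. The acute phase list, with Mt1 and Mt2 as its 2 of 25 rises, had an adjusted p = 0.13 (0.761 with an estimated correlation). It had 0.00107 without the clock-shifted libraries (0.00107 to 0.761 over all alternatives). Median, mean and test differed in sign for the circadian clock (0.16, -0.17, up), neutrophil and monocyte markers (0.04, -0.25, down), xenobiotic metabolism (0.06, -0.04, up) and gluconeogenesis (0.00, -0.15, down).

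Single libraries and the clock-shifted libraries also weigh on the re-fed lists. Without the clock-shifted libraries the endothelial and fatty acid synthesis lists kept their calls. Fatty acid oxidation (adjusted p = 0.543, 0.000169 to 0.738 over all alternatives) and the unfolded protein response (0.392, 4.13e-05 to 0.677 over all) turned direction. The cholesterol (0.0586, 3.97e-11 to 0.663 over all), interferon (0.342, 9.37e-06 to 0.677 over all) and immediate early (0.0762, 8.84e-05 to 0.663 over all) lists lost theirs. So did the cell cycle (0.181), lipid droplet proteins (0.368), oxidative phosphorylation (0.342) and ribosome biogenesis (0.0586), 9 of 11 in all. Cell cycle was lost without control ASO 2 (0.108), 3 (0.211) and PLIN5 ASO 1 (0.0793) and 3 (0.0679; 0.0102 to 0.663 over all). Fatty acid oxidation was lost without control ASO 3 (0.267), 5 (0.15) and PLIN5 ASO 1 (0.487) and 2 (0.0693). Lipid droplet proteins were lost without control ASO 3 (0.0736), 5 (0.0736) and PLIN5 ASO 1 (0.141) and 2 (0.0684; 0.00574 to 0.677 over all). Oxidative phosphorylation was lost without control ASO 1 (0.0502), 3 (0.0736), 5 (0.0767) and PLIN5 ASO 2 (0.325), and with the length trend taken out turned direction (0.971; 0.00697 to 0.971 over all). Ribosome biogenesis was lost without control ASO 1 (0.268), 5 (0.105) and PLIN5 ASO 2 (0.213), 3 (0.142) and 4 (0.0622; 0.00733 to 0.677 over all). The unfolded protein response was lost without control ASO 3 (0.197) and 5 (0.152).

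Autophagy and inflammation are the processes the series title names. In fasted liver none of the autophagy core genes (0 of 38) or lysosome genes (0 of 38) passed edgeR's test, adjusted over all genes or over the list alone, and the lists had adjusted p of 0.704 and 0.746 (medians -0.01 and -0.01). Over all genes, 2003 had an unadjusted p under 0.05 in that comparison, and DESeq2 called 432. EdgeR called 1.17% of all genes tested there, so 0 of 38 lies close to that share. In the simulated data 50.6% of genes set at 1.5-fold were found in this comparison, so smaller changes can be missed. These are RNA levels, and autophagy itself was not measured here. In re-fed liver the same lists had adjusted p of 0.601 and 0.0511, with 0 of 38 genes called in each (1 rose in the autophagy core, and 2 rose and 1 fell in the lysosome list, adjusted over the list alone). None of the fixed autophagy, sirtuin and inflammation genes passed in either state. Fasted log2 fold changes were 0.14 for Ulk1 (SE 0.09), -0.03 for Becn1 (SE 0.06), -0.21 for Atg7 (SE 0.09), 0.17 for Map1lc3b (SE 0.10), -0.02 for Sqstm1 (SE 0.12), -0.42 for Tfeb (SE 0.16) and -0.11 for Lamp1 (SE 0.07), with adjusted p of 0.213 to 0.953. Sirt1, a deacetylase gene (-0.11, SE 0.10), Ppargc1a, a coactivator of mitochondrial genes (0.36, SE 0.21), and Plin2, another lipid droplet coat gene (0.06, SE 0.19), had adjusted p of 0.668, 0.451 and 0.917. Il1b stood at -0.11 (SE 0.65), Ccl2 at -0.83 (SE 0.75) and Nfkb1 at -0.01 (SE 0.09), with adjusted p of 0.959, 0.66 and 0.977. In re-fed liver Map1lc3b came closest, at 0.36 (SE 0.09, adjusted p = 0.0554). Sirt1 stood at -0.20 (SE 0.09), Nfkb1 at -0.21 (SE 0.09), Ppargc1a at 0.04 (SE 0.20) and Ccl2 at -1.28 (SE 0.72), with adjusted p of 0.192 to 0.944. Tnf (39 counts over all 19 libraries, 0 to 6 in each) and Il6 (22 counts, 0 to 6 in each) fell below the filter on low counts, so a difference in them was not detectable at this depth.

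The ASO changed 20 genes in the same direction in both feeding states, more than expected for independent genes: 11 rose (0.65 expected, Fisher's exact p = 3.98e-11) and 9 fell (0.429 expected, Fisher's exact p = 3.72e-10), and 0 were called in opposite directions. Fisher's test takes genes as independent, which they are not, so its p-values do not measure replication across mice. The count was 8 with fasted control ASO 3 and 4 as 1 sample, 13 without the clock-shifted libraries, 3 at adjusted p under 0.01 and 59 in DESeq2. Among those named by the fixed rule, Mt2, Armcx4, Nlrp12, Fbxo36 and Otc rose and Plin5, Ncam2 and Plk2 fell in both. Plk2, which encodes a polo-like kinase, fell from 9.87 to 3.79 CPM in fasted and from 10.4 to 5.23 CPM in re-fed liver. Ncam2, a cell adhesion gene on chromosome 16 (81200697 to 81626828, plus strand), fell from 2.19 CPM to 0.475 CPM in fasted and from 2.67 CPM to 0.585 CPM in re-fed liver. The other 12 were picked out after their values were seen. Among them are Rbm14 (-1.09, SE 0.11 and -0.70, SE 0.11), Cd38 (-0.78, SE 0.17 and -1.13, SE 0.16), Abca3 (-0.82, SE 0.14 and -0.70, SE 0.13) and Il1r1, the interleukin 1 receptor gene (1.01, SE 0.18 and 0.75, SE 0.17). Across all 13293 genes the log2 fold changes of the 2 states were hardly related (Pearson's r 0.06, Spearman's rho 0.08 across genes, which are not independent replicates). The clock-shifted libraries lie in the PLIN5 ASO group in fasted liver and in the control ASO group in re-fed liver. They can thus push the 2 sets of fold changes apart. A trend with transcript length was seen in re-fed liver only (rho -0.332, against 0.024 in fasted liver). The low correlation therefore cannot tell whether the ASO effects themselves differ between the states.

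Re-feeding under control ASO asks which genes respond to food. Fatty acid and cholesterol synthesis genes rose and fatty acid oxidation genes fell. Fasn, the fatty acid synthase gene (chromosome 11, 120805846 to 120824547, minus strand), rose from 78.9 CPM ± 18.1 (SD, n = 4) to 999 CPM ± 284 (SD, n = 5), a log2 fold change of 3.66 (SE 0.28, adjusted p = 5.72e-07). Acly (2.28, SE 0.22), Acaca (1.73, SE 0.22) and Pgd (1.08, SE 0.13) rose with it, 18 of 22 genes of fatty acid synthesis in all (19 adjusted over the list alone; adjusted p = 2.77e-29, and adjusted p = 0.0142 with an estimated correlation). In cholesterol synthesis 22 of 25 rose (24 adjusted over the list alone; adjusted p = 6.34e-30, and adjusted p = 0.0218 with an estimated correlation), among them Fdps (3.82, SE 0.43, adjusted p = 3.21e-05), Dhcr7 (1.98, SE 0.23) and Lss (1.64, SE 0.16). In fatty acid oxidation and ketogenesis 25 of 31 fell (29 adjusted over the list alone; adjusted p = 1.76e-36, and adjusted p = 0.0241 with an estimated correlation). Acadm (-1.02, SE 0.12), Hadhb (-0.91, SE 0.10) and Cpt2 (-0.68, SE 0.08), of the breakdown of fatty acids in mitochondria, were among them. The largest falls were in Cyp4a14 (-5.30, SE 1.05; 1444 to 36.6 CPM), Cyp4a10 (-3.91, SE 0.78) and Cyp4a31 (-3.27, SE 0.41), which encode fatty acid hydroxylases and are close paralogs. Next came Mt2 (-3.21, SE 0.66), Acot1 (-2.76, SE 0.54), Mt1 (-2.71, SE 0.55) and Vnn1 (-2.71, SE 0.60), each lower than every fasted library in 5 of 5. Beside Fdps, the largest rises were in Moxd1 (7.29, SE 2.22), Mup8 (6.97, SE 2.25), Chrna4 (5.12, SE 0.88), Npas2 (4.62, SE 1.44), Rnase2a (4.56, SE 0.99), Pnpla3, a lipid droplet hydrolase gene (4.30, SE 0.64), and Clic3 (3.71, SE 0.99). Moxd1 and Npas2 moved with the clock-shifted libraries. Mup8 rested on re-fed control ASO 5 alone, which held 933 CPM, with the nearest library of its group at 4.81 CPM. Without the clock-shifted libraries the log2 fold changes of Moxd1, Mup8 and Npas2 were 0.15 (adjusted p = 0.978), 0.15 (0.954) and -0.34 (0.84). Over all alternatives their adjusted p ran from 0.000107 to 0.978, 0.000252 to 0.954 and 0.00766 to 0.961. In all, 1759 genes changed (853 rose, 906 fell; 184 and 96 at least 2-fold).

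Smaller shifts under control ASO touched lipid droplet, autophagy and lysosome genes. Plin2 fell by 0.82 (SE 0.19, adjusted p = 0.00771), from 535 to 303 CPM. Hsd17b11 (-1.10, SE 0.13), Pnpla2, the gene of adipose triglyceride lipase (-0.83, SE 0.17), and Mgll, that of monoglyceride lipase (-0.70, SE 0.15), fell too. In all 5 of 20 lipid droplet genes fell (6 adjusted over the list alone; adjusted p = 1.79e-05, and adjusted p = 0.403 with an estimated correlation). In the autophagy core 2 genes rose and 6 fell of 38 (3 and 7 adjusted over the list alone; adjusted p = 0.0479, and adjusted p = 0.605 with an estimated correlation). The kinase gene Ulk1 rose by 0.59 (SE 0.09, adjusted p = 0.000274), and Gabarapl1 (-0.83, SE 0.14), Map1lc3a (-0.57, SE 0.11) and Atg4d (-0.48, SE 0.09) fell. Map1lc3b fell by 0.36 (SE 0.10, adjusted p = 0.0174; without fasted control ASO 3 0.054 and without the clock-shifted libraries 0.12; 0.00466 to 0.12 over all alternatives). In the lysosome list 1 rose and 7 fell of 38 (2 and 10 adjusted over the list alone; adjusted p = 0.0115, and adjusted p = 0.612 with an estimated correlation), with Psap (-0.45, SE 0.08), Neu1 (-0.40, SE 0.08) and Gaa (-0.37, SE 0.08) among the falls. The interferon response moved down, with 7 falls such as Ifit1 (-1.30, SE 0.24) and 1 rise in 31 genes (adjusted p = 0.000135, and adjusted p = 0.612 with an estimated correlation). The unfolded protein and integrated stress response moved up, with 5 rises and 1 fall in 26 (adjusted p = 0.00682, and adjusted p = 0.823 with an estimated correlation). Cell cycle genes moved up with Rrm2 (1.83, SE 0.29), Mki67 and Ccna2 of 21 (adjusted p = 0.0335, and adjusted p = 0.605 with an estimated correlation). Oxidative phosphorylation moved down with Cox4i1 (-0.30, SE 0.09) of 27 (adjusted p = 0.0291, and adjusted p = 0.845 with an estimated correlation). The other 19 lists had adjusted p of 0.0704 to 0.801. Median, mean and test differed in sign in 7 of them: immediate early genes, inflammatory signalling, pancreas, fat and blood markers, p53 targets, circadian clock, lymphocyte markers and acute phase. Without the clock-shifted libraries the unfolded protein list, whose scores were 0.67 and 0.63 in re-fed control ASO 3 and 5 and -0.38 to 0.14 in the other re-fed control libraries, had an adjusted p = 0.574 (4.29e-05 to 0.823 over all alternatives). Calls were lost there too for lysosome (0.0553, 0.00183 to 0.612 over all), oxidative phosphorylation (0.124), cell cycle (0.0697) and autophagy core (0.0957). Without fasted control ASO 3 or 4 the number of genes changed was 1121 or 1169, and without the clock-shifted libraries 1165. Calls were lost for oxidative phosphorylation without fasted control ASO 3 (0.109) or 4 (0.101; 0.00455 to 0.845 over all alternatives). They were lost for the cell cycle without fasted control ASO 1 (0.0831), re-fed control ASO 2 (0.0718) or 3 (0.0977; 0.00777 to 0.605 over all). The autophagy core lost its call without fasted control ASO 3 (0.0816), 4 (0.0748), re-fed control ASO 2 (0.096) or 3 (0.0657; 0.0149 to 0.605 over all). Of the 16 largest changes, Moxd1, Mup8, Npas2 and Clic3 lost their calls in some of these runs. Without fasted control ASO 1, 3, 4 and 5 these were 3, 4, 3 and 4 genes, and without re-fed control ASO 3 and 5 they were 3 and 3. The highest adjusted p so reached was 0.805, for Mup8 without re-fed control ASO 5 (0.000252 to 0.954 over all its alternatives). Of all 83 genes called that the rule takes here, list members included, 60 passed in every run that left out 1 library and 58 without the clock-shifted libraries.

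**Figure D4:**
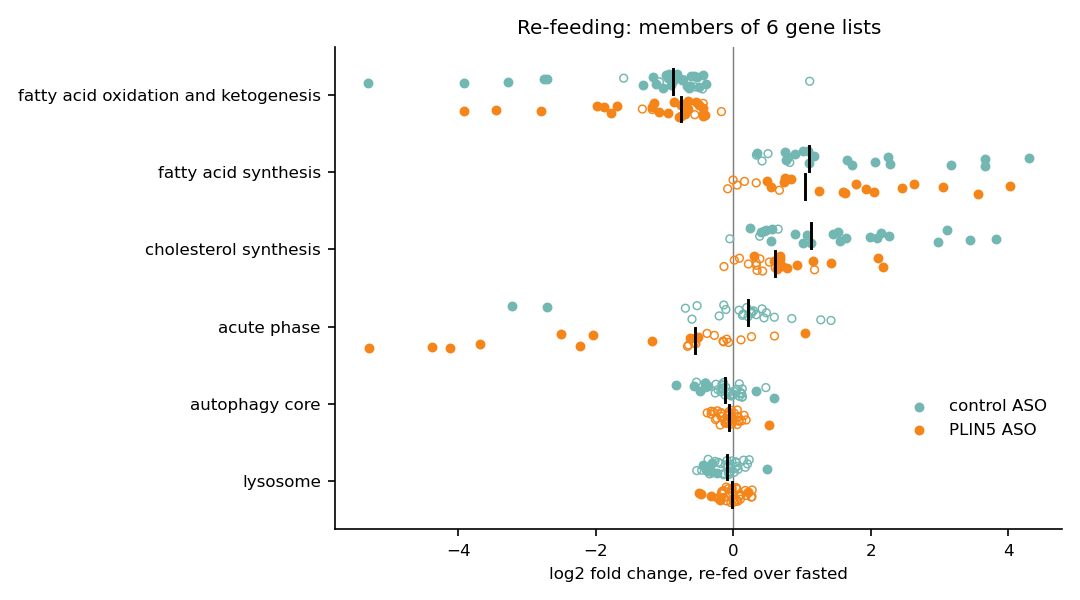
Log2 fold change, re-fed over fasted (horizontal axis), of the members of 6 gene lists under control ASO and under PLIN5 ASO; points are genes, filled where the adjusted p is under 0.05, and black bars are list medians. Fatty acid oxidation and ketogenesis has medians of -0.88 and -0.76, fatty acid synthesis 1.09 and 1.04, and cholesterol synthesis 1.12 and 0.61.

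Re-feeding under PLIN5 ASO asks the same with Plin5 lowered. Fatty acid and cholesterol synthesis again moved up and fatty acid oxidation down, while lipid droplet proteins and lipases were not called (adjusted p = 0.207). Fasn rose from 59.3 CPM ± 5.02 (SD, n = 5) to 701 CPM ± 261 (SD, n = 5), a log2 fold change of 3.56 (SE 0.25, adjusted p = 8.5e-08). With it rose Pklr, the gene of liver pyruvate kinase (2.63, SE 0.31), and the transcription factor gene Srebf1 (2.45, SE 0.30). In all 16 of 22 genes of fatty acid synthesis rose (17 adjusted over the list alone; adjusted p = 1.99e-30, and adjusted p = 0.0119 with an estimated correlation). Slc2a4 (4.20, SE 0.82), Pnpla3 (4.01, SE 0.65), Chrna4 (3.75, SE 0.81) and Hcn3 (3.63, SE 0.48) were the other largest rises. Hcn3 (chromosome 3, 89146074 to 89160196, minus strand) overlaps the end of Pklr on the other strand, and the strand setting is not given in the sources used here. Limma on the deposited FPKM without a filter gave Hcn3 -0.02 (adjusted p = 0.51; 4.43e-10 to 0.51 over all alternatives). In fatty acid oxidation and ketogenesis 25 of 31 fell (29 adjusted over the list alone; adjusted p = 9.28e-39, and adjusted p = 0.0242 with an estimated correlation), such as Cyp4a31 (-3.46, SE 0.40), Hadhb (-0.95, SE 0.10) and Hadha (-0.70, SE 0.08). Cyp4a14 fell by 3.92 (SE 0.97, adjusted p = 0.0163). In cholesterol synthesis 12 of 25 rose (17 adjusted over the list alone; adjusted p = 1.63e-12, and adjusted p = 0.232 with an estimated correlation), with Fdps (2.18, SE 0.37) and Lss (0.71, SE 0.15). Saa2 (-5.30, SE 1.05, adjusted p = 0.00372), Saa3 (-4.37, SE 0.87), Saa1 (-4.12, SE 0.98) and Lcn2 (-3.68, SE 0.70) were, together with Cyp4a14, the largest falls. In the acute phase list 10 fell and 1 rose of 25 (13 and 1 adjusted over the list alone; adjusted p = 1.38e-05, and adjusted p = 0.619 with an estimated correlation). Plin2 fell by 1.02 (SE 0.18, adjusted p = 0.0015) and Ulk1 rose by 0.52 (SE 0.08, adjusted p = 0.000477). All 10 of these largest changes passed in every run that left out 1 library. Of all 66 genes called that the rule takes here, list members included, 49 did so, and 52 passed without the clock-shifted libraries. In all, 1148 genes changed (598 rose, 550 fell; 94 and 106 at least 2-fold), 734 without fasted PLIN5 ASO 5 and 749 without re-fed PLIN5 ASO 3.

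With re-feeding under PLIN5 ASO 8 of 22 genes of amino acid catabolism and the urea cycle rose (9 adjusted over the list alone; adjusted p = 1.96e-05, and adjusted p = 0.312 with an estimated correlation), among them Cps1 (0.58, SE 0.09), Arg1 (0.65, SE 0.10) and Gls2 (0.64, SE 0.12). Interferon response genes moved down with 6 of 31, such as Rsad2 (-0.78, SE 0.14) and Gbp6 (-1.02, SE 0.22), with an adjusted p = 1.46e-05 (adjusted p = 0.619 with an estimated correlation). Ribosome biogenesis moved up with 5 rises and 1 fall in 27 (adjusted p = 0.00435, and adjusted p = 0.625 with an estimated correlation), Mybbp1a (0.36, SE 0.08) and Rrp9 (0.51, SE 0.12) among them. Inflammatory signalling moved down with 4 of 26, which include Nfkbia (-0.83, SE 0.14) and Il1rn (-1.87, SE 0.39; adjusted p = 0.0308, and adjusted p = 0.625 with an estimated correlation). Oxidative phosphorylation moved up with Ndufs8 and Sdhb of 27 (each 0.37; adjusted p = 0.00982, and adjusted p = 0.644 with an estimated correlation). Kupffer cell and macrophage markers (0 of 16; adjusted p = 0.0151) and stellate cell and fibroblast markers (0 of 14; adjusted p = 0.0247) moved down, with adjusted p of 0.644 and 0.625 with an estimated correlation. The other 18 lists had adjusted p of 0.129 to 0.796. The autophagy core, with Ulk1 as its only call, had 0.192 and the lysosome list 0.352. Median, mean and test differed in sign in 7 of these: lipid droplet proteins, bile acid synthesis and transport, cell cycle, pancreas, fat and blood markers, xenobiotic metabolism, unfolded protein response and p53 targets. Without fasted PLIN5 ASO 3, fasted PLIN5 ASO 5 and re-fed PLIN5 ASO 2 the calls of Kupffer cell markers (0.363, 0.105 and 0.172; 0.00026 to 0.644 over all alternatives), stellate cell markers (0.11, 0.113 and 0.147, and 0.0547 without fasted PLIN5 ASO 4; 0.00174 to 0.625 over all) and inflammatory signalling (0.272, 0.0965 and 0.104; 0.00917 to 0.702 over all) were lost. Oxidative phosphorylation lost its call without fasted PLIN5 ASO 3 (0.166) and re-fed PLIN5 ASO 2 (0.16; 0.00131 to 0.644 over all), and ribosome biogenesis without the clock-shifted libraries (0.0923; 0.000468 to 0.625 over all). Without these the Kupffer cell (0.6), stellate cell (0.6), inflammatory (0.702) and oxidative phosphorylation (0.6) calls were lost as well.

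Genes called under re-feeding were shared between the ASOs well beyond the number expected for independent genes: 222 rose in both (38.4 expected, Fisher's exact p = 9.3e-117), 268 fell in both (37.5 expected, Fisher's exact p = 1.73e-173) and 2 were called in opposite directions. These p-values too take genes as independent and do not measure replication across mice. The log2 fold changes were related across genes (Pearson's r 0.376, Spearman's rho 0.321; genes are not independent replicates). Whether the response to food itself differed between the ASOs was tested as the interaction, the re-fed ASO effect minus the fasted ASO effect. Of 13293 genes 3 passed. Among them were Dpm3, of dolichol-mannose synthesis (0.60, SE 0.10), and Rnf144b (-1.19, SE 0.20), each with an adjusted p = 0.0482. Each lost its call in runs that left out 1 library, and 0 to 3 genes passed in such runs. Over all alternatives the adjusted p ran from 0.000369 to 0.185 for Dpm3 and from 7.93e-05 to 0.167 for Rnf144b. The count was 0 without fasted control ASO 1, 3, 4 or 5, fasted PLIN5 ASO 1, 3, 4 or 5, re-fed control ASO 1 or 2, or re-fed PLIN5 ASO 2 or 3, and 1 without re-fed control ASO 3 or re-fed PLIN5 ASO 1. At an unadjusted p under 0.05 there were 1991 genes, against 665 by chance, and DESeq2 called 93. All 4 clock-shifted libraries lie in the groups that count negatively in the interaction, fasted PLIN5 ASO and re-fed control ASO. The clock shift therefore adds to it in full. The interaction also fell with transcript length (Spearman's rho -0.268 across genes). An excess over chance here need not come from the ASO changing the response to food.

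By list, and relative to other genes, the interaction was negative for cholesterol synthesis (median -0.73; adjusted p = 1.68e-08), with Lss at -0.93 (SE 0.21, adjusted p = 0.118) and Idi1 at -2.83 (SE 0.75, adjusted p = 0.168). It was also negative for the acute phase list (median -0.41; adjusted p = 1.3e-05), with Saa2 at -6.57 (SE 1.44, adjusted p = 0.118). It was negative for Kupffer cell and macrophage markers (adjusted p = 2.75e-05), stellate cell and fibroblast markers (adjusted p = 5.92e-05) and the unfolded protein and integrated stress response (adjusted p = 0.0137). It was positive for oxidative phosphorylation (adjusted p = 3.45e-07), lipid droplet proteins and lipases (adjusted p = 0.00235), xenobiotic metabolism (adjusted p = 0.0137) and amino acid catabolism (adjusted p = 0.04). No gene of these 9 lists passed edgeR's test over all genes. Adjusted over the list alone, 10 of cholesterol synthesis fell, and 2 of the acute phase list rose and 10 fell. Each list had an adjusted p = 0.566 with an estimated correlation. The other 20 lists had adjusted p of 0.0822 to 0.865. Median, mean and test differed in sign for circadian clock, autophagy core, p53 targets, pancreas, fat and blood markers and interferon response. The xenobiotic call was lost without fasted control ASO 3 (0.0599), 4 (0.0916) and fasted PLIN5 ASO 3 (0.0747; 0.000213 to 0.931 over all alternatives). The unfolded protein call was lost without fasted PLIN5 ASO 1 (0.064), re-fed control ASO 3 (0.0842) and 5 (0.112; 0.00016 to 0.957 over all). The amino acid call was lost without fasted control ASO 1 (0.0527), 3 (0.068) and 4 (0.0981), fasted PLIN5 ASO 1 (0.0762), 3 (0.0807) and 4 (0.0736), re-fed control ASO 4 (0.0825) and 5 (0.112) and re-fed PLIN5 ASO 2 (0.0781; 0.00744 to 0.566 over all). Without the clock-shifted libraries 6 of the 9 calls were lost: acute phase (adjusted p = 0.27, 1.16e-09 to 0.566 over all), Kupffer cell markers (0.168, 2.09e-07 to 0.566 over all) and lipid droplet proteins (0.465, 0.000318 to 0.566 over all). The others lost were the unfolded protein response (0.223), xenobiotic metabolism (0.931) and amino acid catabolism (0.223).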

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

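The tests below on the acute phase, clock and length patterns were chosen after those results were seen, apart from the length trend without ribosomal and mitochondrial protein families and the splits outside the fasted ASO comparison, whose bounds were written beforehand.

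Acute phase genes such as Saa1, Saa2 and Lcn2, with 2 of 16 macrophage and 3 of 14 stellate cell markers, stood higher in fasted PLIN5 ASO liver, though with an estimated correlation the macrophage (adjusted p = 0.526) and stellate (0.154) lists were not called, nor the macrophage list without the clock-shifted libraries (0.275). Whether the clock-shifted libraries carry the acute phase rise stays open: without them the list had an adjusted p of 1.13e-06 (0.385 with an estimated correlation), but its score, at 1.42, -0.28 and 0.00 in PLIN5 ASO 1, 2 and 4, had an exact permutation p = 0.0857 (two-sided, 35 splits). A lower share of hepatocytes could raise all other cell types alike. The macrophage minus endothelial score stood at 0.460 with PLIN5 ASO and -0.336 with control ASO (exact permutation p = 0.0159, two-sided, 126 splits). Alone, the macrophage, stellate and endothelial scores had exact permutation p of 0.198, 0.0873 and 0.0794. This contrast was chosen after the lists were seen to move apart, and it cannot decide the question. PLIN5 ASO 3 and 5, where the macrophage score rose, also held the highest neutrophil, lymphocyte and stellate scores of their group. Their endothelial scores were the highest of the group too (0.06 and -0.01, against -0.42, -0.38 and -0.23). A response of single mice apart from the ASO may remain, since the acute phase score of 0.761 against -0.307 has an exact permutation p = 0.0714 and PLIN5 ASO 2 and 4 lie among or near the controls. Health records of the mice and further animals would be needed to decide.

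Fasted PLIN5 ASO 3 and 5 and re-fed control ASO 3 and 5 had clock scores of 0.00, -1.43, -0.15 and 2.26, against -6.65 to -4.31 in the other 15 libraries. Labels swapped between these groups are argued against by Fasn, which stood at no more than 60.4 CPM in the 2 fasted libraries (53.9 to 65.2 CPM in their group) and at no less than 707 CPM in re-fed control ASO. A batch shared by libraries numbered 3 and 5 is argued against as well, as the highest clock score of these numbers in the other groups was -4.90. Another time of sampling or feeding may set these 4 apart, with the lowest of their scores at -1.43, and no time of day is given in the sources used here.

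In re-fed liver short transcripts stood higher and long ones lower with PLIN5 ASO than with control ASO. Long minus short transcripts differed between re-fed and fasted control ASO (0.20 against -0.05, exact permutation p = 0.0159, two-sided, 126 splits). Between re-fed and fasted PLIN5 ASO no difference was detected (-0.12 against -0.04, exact permutation p = 0.341, two-sided, 252 splits). The origin of this trend therefore need not lie in PLIN5 ASO liver. Ribosomal and mitochondrial protein genes alone do not make this trend, since rho was -0.313 across the 12484 genes left without 301 members of such families. A length trend of the libraries could account for part of the folds: with it taken out 39 genes were called, 37 of them among the 183, and the median absolute log2 fold change of the 183 went from 0.42 to 0.33 (median SE 0.09 and 0.08). All 183 kept their direction and 85.8% had a smaller fold, so calls ended with shrinking folds, not with turned ones. Separate preparation of the re-fed groups may lie behind it (exact permutation p = 0.00794 for long minus short transcripts, two-sided, 252 splits), but group and preparation cannot be told apart, as no preparation dates are given in the sources used here.

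Other splits of the libraries into groups put the counts of calls beside chance. Of 100 splits, the real one included, 1 gave as many genes as the real split in each comparison: 156 in fasted ASO (highest other 69), 183 in re-fed ASO (43), 1759 in re-feeding under control ASO (1024), 1148 under PLIN5 ASO (19) and 3 in the interaction (1), so chance can be excluded at 1 in 100 for the edgeR gene counts of the re-fed ASO comparison and of re-feeding under PLIN5 ASO. For fasted ASO and re-feeding under control ASO this holds only if fasted control ASO 3 and 4 are separate mice, as the splits took them to be. Taken as 1 sample, these libraries give 36 genes in fasted ASO, 1153 in re-feeding under control ASO and 0 in the interaction, and no splits were drawn for that setting. The interaction splits redrew the ASO labels within each feeding state. They test for no ASO effect at all, not for an equal effect in both states, so chance cannot be excluded for the 3 interaction genes. The split with 1024 genes keeps all 4 fasted control libraries together with re-fed control ASO 4, so it is the real split with 1 library moved. Chance aside, the splits cannot tell the ASO from another difference between the groups. In re-fed liver the clock-shifted libraries all lie in control ASO and the length trend differs by group. With that trend taken out 39 genes passed in re-fed ASO. For the number of lists called chance cannot be excluded: 18 of 100 splits gave as many as the real 12 in fasted ASO (highest other 15), 9 as many as 11 in re-fed ASO (12), 23 as many as 10 in re-feeding under control ASO (14), 29 as many as 11 under PLIN5 ASO (15) and 40 as many as 9 in the interaction (17).

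Single libraries stood far from the rest of their group by Dixon's test in 37 of 388 groups tested, where chance alone gives about 1 in 20, or 19, for independent and normally distributed values. Genes such as Fos, Egr1 and Nr4a1 stood out together in the same library and are counted singly. The excess over 19 therefore cannot be read as beyond chance. Total counts, in units of 1e6, were 28.2 in fasted control ASO 5 (nearest 33.1) and 66.9 in re-fed PLIN5 ASO 5 (nearest 28.4). Fasted control ASO 1 stood apart in CPM of Asns (1.86), Fos (17.9), Moxd1 (1.11), Mt1 (69.4), Slc13a2 (2.03) and Sqstm1 (369) and in its scores for ribosome biogenesis (-0.19) and endothelial markers (-0.16). Fasted control ASO 5 did in Hcn3 (14.6), Ppargc1a (5.13) and Rnf144b (26.6) and the amino acid score (-0.21). In fasted PLIN5 ASO, library 1 did in the p53 score (-0.42), library 3 in Mup8 (558) and library 4 in LOC100504703 (5.02) and Ulk1 (69.1). In re-fed control ASO, library 3 did in Lcn2 (13.0), library 4 in Becn1 (35.6) and library 5 in Egr1 (109), Fos (136), Il1b (5.96), Mup8 (933), Nr4a1 (79.1), Rnf125 (83.6) and Wfdc17 (9.12). In re-fed PLIN5 ASO, library 1 did in Cyp4a10 (375) and Cyp4a14 (369), library 2 in Hamp2 (135), Tfeb (14.7) and its inflammatory (-0.37) and stellate (-0.46) scores, library 4 in Npm3 (8.89), Rnf144b (33.3) and the lymphocyte score (-0.32), and library 5 in Saa1 (277).

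In the main fit the interaction passed edgeR's test for Rnf144b (-1.19) and Dpm3 (0.60), each with an adjusted p = 0.0482. Neither was called without the clock-shifted libraries (adjusted p = 0.123 for Rnf144b and 0.185 for Dpm3). The same held with the clock covariate (0.114 for each) and with length offsets (0.0965 for Rnf144b and 0.16 for Dpm3). The splits above cannot exclude chance for these genes, as they do not test for an equal effect in both states. Relative to other genes (camera), interaction effects lay to one side for the lists of cholesterol synthesis (adjusted p = 1.68e-08, negative), acute phase (1.3e-05, negative), Kupffer cell and macrophage markers (2.75e-05, negative), stellate cell and fibroblast markers (5.92e-05, negative), unfolded protein and integrated stress response (0.0137, negative), oxidative phosphorylation (3.45e-07, positive), lipid droplet proteins (0.00235, positive), xenobiotic metabolism (0.0137, positive) and amino acid catabolism (0.04, positive). Each of these lists had an adjusted p = 0.566 with an estimated correlation, and 0 of the 9 differed from no effect in fry. Of the 9, 6 were not called without the clock-shifted libraries: acute phase (0.27), Kupffer cell markers (0.168), unfolded protein response (0.223), lipid droplet proteins (0.465), xenobiotic metabolism (0.931) and amino acid catabolism (0.223).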

How the results depend on the processing

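The alternatives with fasted control ASO 3 and 4 as 1 sample, without the clock-shifted libraries, with the clock score as a covariate and with length offsets were chosen after the data were seen. Genes changed in fasted ASO (156) were 432 in DESeq2, 253 with the replicate block, 70 in limma on log2(FPKM + 1) without a filter, 36 with fasted control ASO 3 and 4 as 1 sample and 236 with the clock covariate; lists called (12) were 0 with an estimated correlation and 4 in fry. In re-fed ASO genes (183) were 588 in DESeq2, 4 in a fit of only the groups compared, 290 with the replicate block, 45 without the clock-shifted libraries and 39 with length offsets; lists (11) were 3 without the clock-shifted libraries, 6 with the covariate, 0 with an estimated correlation and 1 in fry. For re-feeding under control ASO genes (1759) were 1153 with fasted control ASO 3 and 4 as 1 sample and 1165 without the clock-shifted libraries, and lists (10) were 6 with the covariate and 3 with an estimated correlation. For re-feeding under PLIN5 ASO lists (11) were 7 with the covariate, 2 with an estimated correlation and 4 in fry. For the interaction genes (3) were 93 in DESeq2, 1 with the replicate block, and 0 without a filter, in limma on log2(FPKM + 1) or log2(FPKM + 0.1), with fasted control ASO 3 and 4 as 1 sample, with the covariate and with length offsets; lists (9) were 5 without the clock-shifted libraries, 0 with an estimated correlation and 0 in fry. Genes changed by the ASO in both states (20) were 3 at adjusted p under 0.01, 59 in DESeq2, 8 with fasted control ASO 3 and 4 as 1 sample and 13 without the clock-shifted libraries; genes changed by re-feeding under both ASOs (490) were 208 at adjusted p under 0.01. Leaving out 1 library at a time, the Plin5 log2 fold change lay between -2.18 and -1.90 in fasted and between -2.48 and -2.12 in re-fed liver. Genes changed lay between 24 and 185 (fasted ASO), 45 and 333 (re-fed ASO), 1121 and 1833 (re-feeding, control ASO), 734 and 1170 (re-feeding, PLIN5 ASO) and 0 and 3 (interaction), and lists called between 10 and 15, 6 and 12, 8 and 12, 7 and 13, and 8 and 13. Directions turned in re-fed ASO for fatty acid oxidation (adjusted p = 0.543) and the unfolded protein response (0.392) without the clock-shifted libraries, and for oxidative phosphorylation with length offsets (0.971). They turned for Npas2 in re-feeding under control ASO (log2 fold change -0.34 without the clock-shifted libraries, -0.068 with the covariate) and, under PLIN5 ASO, for Kupffer cell markers without the clock-shifted libraries (adjusted p = 0.6) and for Hcn3 in limma on log2(FPKM + 1) without a filter (log2 fold change -0.02). The interaction of the unfolded protein response turned without the clock-shifted libraries (adjusted p = 0.223) and with the covariate (0.957). The cause of these differences was not tested. A check of the replicate block left open whether replicate numbers pair libraries. Residuals of like-numbered libraries correlated at -0.21 to 0.17, with 3 of 5 pairs over 0.1 in re-fed ASO and 2 of 5 in re-feeding under PLIN5 ASO. The like-numbered library was the best match in 2 of 4, 2 of 5, 2 of 4 and 1 of 5 cases in fasted ASO, re-fed ASO, re-feeding under control ASO and under PLIN5 ASO. Fasted PLIN5 ASO and re-fed control ASO, which hold the clock-shifted libraries, were not set against each other. With RLE size factors 144 of 145 list tests (29 lists in 5 comparisons) and 671 of 675 tests of named genes stayed on the same side of the threshold in the same direction.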

Other observations

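Gene families and the neighbours of Plin5 were looked at after the values above were seen, among 28 families in 5 comparisons. In re-fed PLIN5 ASO liver 32 of 76 ribosomal protein genes (Rpl, Rps) rose, with a median log2 fold change of 0.33 (adjusted p = 1.78e-37; adjusted p = 0.249 with an estimated correlation). These transcripts are short, and with each library's length trend taken out 0 of 76 rose and the median was 0.17. In fasted PLIN5 ASO liver 3 of 31 collagen genes rose, with a median of 0.63 (adjusted p = 6e-06; adjusted p = 0.191 with an estimated correlation), and with the length trend taken out 3 rose and the median was 0.61. Of 8 tested genes within 60 kb of Plin5, 0 were called lower in either feeding state, which argues against a loss of reads along the locus. Lrg1, which encodes a secreted glycoprotein, rose in fasted liver (1.32, SE 0.28, adjusted p = 0.0258) and stood at 0.49 in re-fed liver (SE 0.25, adjusted p = 0.298). Plin4, the perilipin gene next to Plin5, stood at -0.16 (SE 0.63, adjusted p = 0.935) in fasted and 0.98 (SE 0.61, adjusted p = 0.393) in re-fed liver.

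Fasted control ASO 3 and 4 differed by an SD of 0.0646 on the log2 scale across highly expressed genes, against 0.174 for the next pair and a median of 0.302 over the pairs within groups. They may be 1 animal or 1 RNA sequenced 2 times, which was not tested and which the labels do not settle. With them taken as 1 sample, 36 genes are called in the fasted ASO comparison, against 156. The transcript length trend also differed in re-feeding under control ASO (rho 0.221, exact permutation p = 0.0159, two-sided, 126 splits) and was smaller under PLIN5 ASO (rho -0.06, exact permutation p = 0.341, two-sided, 252 splits).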
